A study of Mus musculus with 6 samples.

How the data were processed

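RNA from 6 mouse mammary tumors was hybridized to Affymetrix Mouse Gene ST arrays, 1 array per tumor, with 3 tumors from water-treated mice and 3 from mice given TKI258. The series text calls them individual tumors and the sample titles call them biological replicates, so the spread within a group is a spread between tumors. The deposited values are log2 signals per probe set, made by the authors with RMA (background correction, normalization across arrays and summary of probes), per the submitters' processing notes, which also name affy and limma without versions. Versions, their order and the genome build are not given in the sources used here. The deposited table held 34760 probe sets and 6 columns, all used, and no probe set carried a control (AFFX) name, so none was removed. No pair of arrays was identical.

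Probe sets were named through the platform annotation. Of all probe sets, 21640 had 1 gene, 1321 had several and 11799 had none listed, and no gene was named from the last 2 kinds. Probe sets without a listed gene may include control features of the array, which the sources used here do not mark. Symbols were checked against the mouse reference gene table (assembly GRCm38.p6) by Entrez number: 21553 probe sets matched and 0 symbols changed. For gene results, each of 19937 genes was represented by its probe set with the highest mean over the 6 arrays; 954 genes had more than 1. No genomic coordinates are reported.

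TKI258 was compared with water in a limma linear model on the log2 values with group as the only term, moderated by eBayes (R 4.3.3, limma 3.58.1), two-sided, without a filter. The p-values were adjusted by the Benjamini-Hochberg method over all probe sets, with a threshold of 0.05. Standard errors (SE) of differences are the moderated ones. Differences are TKI258 minus water in log2 units, and group values are means with the SD over 3 tumors.

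Before the data were examined, 31 gene lists were fixed: targets and feedback genes of the drug, vessel and stromal cells, immune and other cell types that a mammary tumor can hold, and proliferation, death, hypoxia and stress programs. Each list was tested with camera (limma) against all other genes, with a preset correlation of 0.01 between genes and adjustment over the 31 lists. Camera with a correlation estimated from the arrays, and fry, which asks whether the genes of a list move on balance one way, were run beside it. The estimated correlations had a median of 0.408 over the lists, well above the preset 0.01. Camera p-values with the preset correlation can therefore be far too small. Members were also counted with p-values adjusted over the list alone. An exact two-sided permutation test of list means per tumor cannot go below p = 0.1 with 3 tumors against 3. Some genes belong to more than 1 list: Mmp8 and Mmp9 (neutrophil, matrix proteases), Hdc (neutrophil, mast cell), Flt1, Kdr, Pdgfrb, Pdgfra, Kit and Csf1r (target kinases and a cell type), Egr1 (feedback, immediate early) and Sesn2 (apoptosis, integrated stress). List members without a probe set of their own were not analysed here, among them Ccnb1, Cdkn1a, Bax, Lck, Flg, Cfd and the hemoglobin genes.

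The rule for naming genes was fixed at the same time. It took up to 12 genes per direction with the largest difference among those that passed and whose tumors did not overlap. Where fewer than 5 passed in a direction it took the 6 with the smallest p. It also took the target kinases with Vegfa, Mmp9, Spry4, Dusp6, Etv4, Etv5, Pecam1, Cdh5 and Mki67, 4 members of each list that passed (smallest p in the direction of the list) and at most 2 of each other list. This gave 118 genes. Genes named outside the rule are said to have been chosen after their values were seen.

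The test was tried on 5 sets of simulated arrays with the same 34760 probe sets, in which 200 genes differed between TKI258 and water. It recovered 68.7% of genes with a log2 change of 1, 91.6% at 2 and 98.5% at 3, and 4.96% of called probe sets were unchanged. A list lowered by 0.35 among 19937 genes was called in 100% of the sets and unshifted lists in 0%. The simulated genes vary independently, so these shares say nothing about lists whose genes vary together. Their variances were drawn from the fitted eBayes prior rather than taken from each probe set. With 200 changed genes the adjusted threshold is also easier to reach than with fewer. The shares therefore do not say how many real changes the comparison could have missed.

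The alternatives were a filter on low signal, a filter on low variance, quantile normalization, median centring, a replicate block, each array left out, eBayes with a trend and robust prior, array weights, the mean of all probe sets of a gene, other thresholds, and the other set tests. All were run except another pseudocount, which does not apply to log2 values. After the data were seen, 3 more were added: probe sets with 1 gene only, the removal of both arrays with high B cell markers (water replicate 1 and TKI258 replicate 3), and the B cell list mean as a covariate. Array medians lay between 6.38 and 6.44. After the data were seen, 3 further lists (lymph node stroma, skin and luminal tumor genes) were written for the tests of explanations. The number of arrays limits the precision. Detection calls, scanner images and scan dates were not used here, so signals near background cannot be marked and batches cannot be tested. Kcne3, Lep, Fgf3, Fgf21, Ret, Dsg3 and Ms4a2 are among the genes named below with both group means under every array median.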

Results

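Gene expression was profiled in 6 tumors of 4T1 cells, a mouse mammary carcinoma line, grown in the mammary gland of Balb/C mice. Each mouse received 750000 cells. From day 7 after injection, 3 mice were given water and 3 were given 40 mg/kg of TKI258 by mouth every day for 14 days. TKI258 (dovitinib) inhibits receptor tyrosine kinases, among them receptors of FGF, VEGF and PDGF, KIT, CSF1R and FLT3. Whole tumors were profiled, so signals come from tumor cells together with vessels, stroma, immune cells and any adjacent tissue. Correlations between arrays were 0.988 to 0.992 within the water group and 0.981 to 0.993 within the TKI258 group. The comparison asked which transcripts differed in tumors after treatment.

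The genes that separated the groups most clearly were Igfbp3, which encodes an IGF-binding protein, and Esm1, which encodes the endothelial proteoglycan endocan. Igfbp3 signal was 9.54 ± 0.30 in water tumors and 7.30 ± 0.19 in TKI258 tumors (SD, n = 3), a 4.73-fold lower level. Esm1 was 7.51 ± 0.37 and 5.37 ± 0.17, a 4.41-fold lower level. Mmp3 (stromelysin 1) was 2.19-fold lower, and Clca2, Sema6d and the spindle gene Nusap1 completed the 6 lower genes with the smallest p. Among higher genes, Angpt1, a ligand of the endothelial receptor TIE2, was 8.50 ± 0.18 in water and 10.02 ± 0.50 in TKI258 tumors, a 2.87-fold difference. The receptor gene Ror1 (0.90 ± 0.13, log2 difference ± SE), Slc44a3 (1.13 ± 0.17), Epdr1 (0.66 ± 0.11), Alkbh3os1 (0.51 ± 0.08) and Vmn2r-ps11 (0.58 ± 0.09) were the others. Alkbh3os1, Vmn2r-ps11 and Clca2 had low signals, with TKI258 means of 4.88, 3.73 and 4.61. Both group means of each lay below every array median (6.38 to 6.44). Slc44a3 was below these medians in water (5.35) and Esm1 in TKI258 tumors (5.37). None of these 12 genes passed limma's test over all probe sets: adjusted p was 0.196 for Igfbp3 and Esm1, 0.242 for Mmp3 and 0.484 for the rest. Across the array 0 of 34760 probe sets passed, while 2803 had an unadjusted limma p under 0.05 (1344 higher and 1459 lower), against 1738 expected by chance. A probe set without a single gene (-1.25 ± 0.11) had a smaller limma p than Esm1 and the same adjusted p, 0.196. Of 603 probe sets with unadjusted limma p under 0.01, 262 had no gene listed, against 11799 of all 34760. Some of these may be control features. Of 19937 genes, 1726 had all TKI258 tumors above and 1294 all below the water tumors, 15.1% together, against 10% by chance. Igfbp3 and Esm1 passed when the less variable probe sets were left out (limma adjusted p = 0.00728 and 0.00981). That filter used the SD over all 6 arrays, which includes the group difference. It is thus not independent of the test, and the pass adds no support. Over all alternatives the adjusted p ranged from 0.00728 to 0.727 for Igfbp3 and from 0.00981 to 0.727 for Esm1. Of the 31 gene lists, 17 passed camera with the preset correlation (16 lower and 1 higher; 11 without water replicate 2), and 0 passed with an estimated correlation. Without water replicate 1, 3 other probe sets passed, all lower: Krt1, Krtdap and a probe set with several genes listed.

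**Figure D1:**
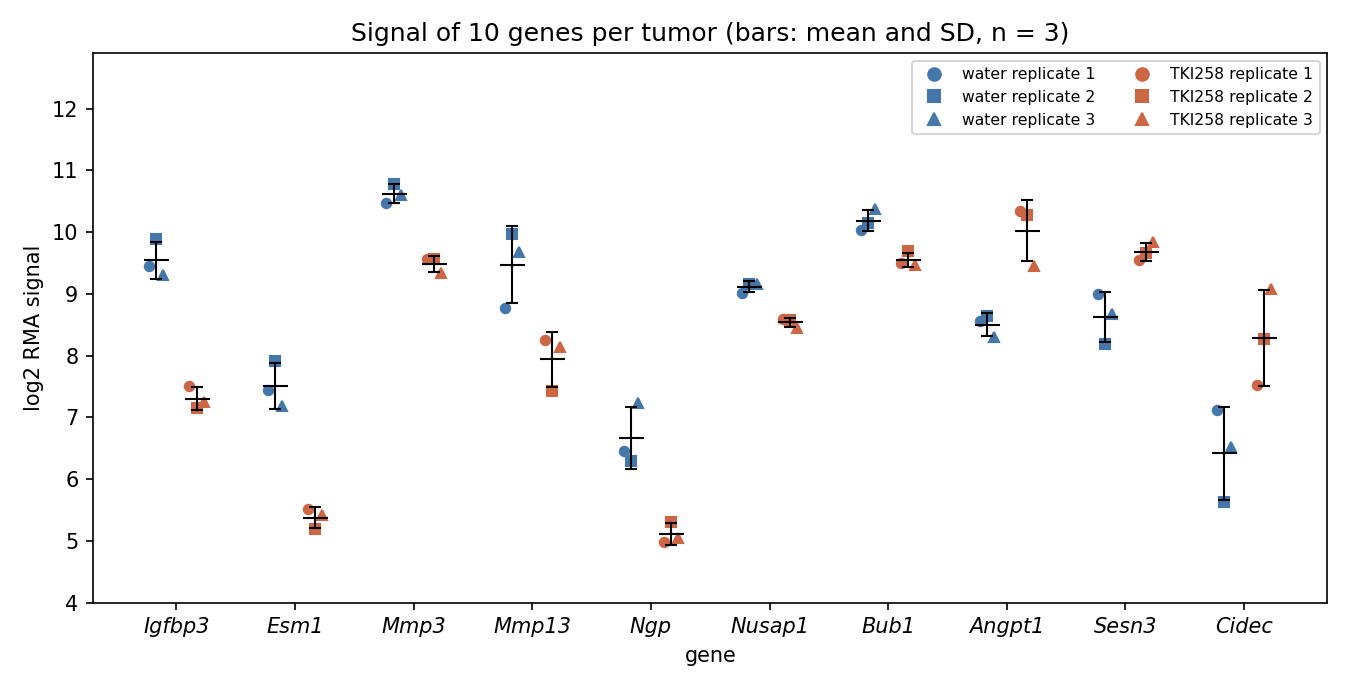
Log2 RMA signal (y axis) of 10 genes (x axis) in each water (blue) and TKI258 (orange) tumor, with mean and SD over 3 tumors as black bars; the genes were picked from those named in the text after their values were seen. Igfbp3 had means of 9.54 and 7.30 and Angpt1 of 8.50 and 10.02, and no TKI258 tumor overlapped a water tumor for any gene shown, although none passed over all probe sets.

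Genes of endothelial tip cells, which lead vascular sprouts, had a lower list mean in TKI258 tumors. The list passed camera with the preset correlation but not with an estimated one. The list mean was 8.23 ± 0.22 in water and 7.52 ± 0.12 in TKI258 tumors (SD, n = 3), a log2 difference of -0.71, with every TKI258 tumor below every water tumor. Of 13 members, 12 were lower, and 9 lower members and 1 higher passed adjusted over the list alone, against 0 over all probe sets. Besides Igfbp3 and Esm1 these were the basement membrane gene Nid2 (-0.92 ± 0.23) and Kcne3 (-0.60 ± 0.15) and, named after their values were seen, Angpt2 (-1.06 ± 0.34), the Notch ligand Dll4 (-0.55 ± 0.14), Col4a1, Col4a2 and Apln. The higher one was the apelin receptor gene Aplnr (0.66 ± 0.13), also named after its value was seen. Camera gave an adjusted p of 6.38e-10 with the preset correlation, and adjusted p = 0.435 with an estimated correlation. The exact permutation p of the list mean was 0.1, the smallest that 3 against 3 tumors allow. In the same tumors the adipocyte list mean differed by 1.20. The number of lower members passing over the list alone was 5 without TKI258 replicate 2 and 3 without both water replicate 1 and TKI258 replicate 3.

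General endothelial genes had a smaller difference. Their list mean differed by -0.16, with 17 of 25 members lower (camera adjusted p = 0.00508, and adjusted p = 0.650 with an estimated correlation). Adjusted over the list alone, Emcn (-0.74 ± 0.16) and Cd93 (-0.88 ± 0.22), both surface proteins of endothelium, were lower and the von Willebrand factor gene Vwf, named after its value was seen, was higher (0.47 ± 0.12). Values that did not pass were -0.51 ± 0.18 for Cdh5, -0.16 ± 0.34 for Pecam1 and 0.04 ± 0.20 for Vegfa. The mural cell list differed by -0.12, with 11 of 15 members lower, led by Mcam (-0.54 ± 0.18), Higd1b, Kcnj8 and Acta2 (camera adjusted p = 0.0293, and adjusted p = 0.435 with an estimated correlation). The endothelial call was lost with the low-signal filter and without water replicate 2 (-0.09), TKI258 replicate 1 (-0.10) or TKI258 replicate 2 (-0.09). The endothelial difference was -0.25 without water replicate 3 and -0.29 without TKI258 replicate 3. Endothelial members passing over the list alone dropped to 0 without any array except water replicate 3, which left 1. They also dropped to 0 after quantile normalization, with the trend and robust prior, with array weights and with the B cell covariate. The mural call was lost with either filter and without water replicate 2 (-0.12) or TKI258 replicate 2 (-0.04).

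The 13 kinases that TKI258 is known to inhibit did not shift as a list (mean difference -0.05, camera adjusted p = 0.605). The FGF receptors differed by 0.00 ± 0.10 (Fgfr1), 0.30 ± 0.13 (Fgfr2), -0.04 ± 0.08 (Fgfr3) and 0.25 ± 0.13 (Fgfr4). The VEGF receptors differed by -0.37 ± 0.13 (Flt1), -0.06 ± 0.22 (Kdr) and 0.02 ± 0.16 (Flt4). Pdgfra, Pdgfrb, Kit, Flt3, Csf1r and Ret differed by 0.10 ± 0.43, -0.19 ± 0.28, -0.56 ± 0.32, -0.19 ± 0.21, -0.21 ± 0.17 and 0.30 ± 0.09, and no kinase passed adjusted over the list alone (1 lower without water replicate 2, where the list mean difference was 0.02). The direction turned for Fgfr1 with median centring (-0.02) and for Flt4 with quantile normalization (-0.02). Feedback genes of FGF and ERK signaling had a list mean difference of -0.12, with 15 of 18 members lower (camera adjusted p = 0.00667, and adjusted p = 0.650 with an estimated correlation). Spry4 (-0.61 ± 0.21), Dusp4 (-0.56 ± 0.20), Etv4 (-0.44 ± 0.19) and Dusp5 (-0.26 ± 0.10) were the lowest in p, Dusp6 and Etv5 differed by -0.07 ± 0.13 and -0.08 ± 0.15, and no member passed adjusted over the list alone. The largest difference of the list was in the other direction, 1.00 ± 0.50 for Spry1, named after its value was seen. This list's direction turned without TKI258 replicate 3 (0.05), whose list mean was 8.55 against 9.07 and 9.05 in the other TKI258 tumors, with array weights (0.01), and without both arrays high in B cell markers (0.02). Its call was also lost with the low-signal filter and without water replicate 2 (-0.06), and its difference was -0.21 without TKI258 replicate 1 and -0.20 without TKI258 replicate 2. The FGF ligand list did not pass (0.08, adjusted p = 0.0778); Fgf3 (0.27 ± 0.09) and Fgf21 (0.27 ± 0.12) had its smallest p, and the list passed higher without water replicate 3 (0.10) and differed by 0.045 without TKI258 replicate 3.

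The lists of cell division genes had lower means in TKI258 tumors, by less than the tip cell list. Neither passed camera with an estimated correlation. The mitosis list mean was 9.64 ± 0.11 in water and 9.29 ± 0.05 in TKI258 tumors (SD, n = 3), a difference of -0.35, and all 23 measured members were lower, 21 of them with no overlap between groups (10% of genes by chance). Adjusted over the list alone 19 passed, against 0 over all probe sets. Nusap1 (-0.58 ± 0.09), the checkpoint kinase gene Bub1 (-0.64 ± 0.12), the spindle assembly factor Tpx2 (-0.50 ± 0.10) and Bub1b (-0.43 ± 0.09) had the smallest p, and Mki67 differed by -0.26 ± 0.09. All 23 measured DNA replication genes were also lower (list mean difference -0.22), with Rrm1, Gins1, Mcm10 and Prim1 between -0.36 and -0.31, and 0 passed adjusted over the list alone. Camera gave adjusted p = 1.15e-22 for mitosis and 1.39e-10 for replication with the preset correlation, and adjusted p = 0.435 with an estimated correlation for both. Many lists share the value 0.435 through the adjustment. Before adjustment, camera with an estimated correlation gave p = 0.0337 for mitosis, 0.0338 for tip cell and 0.106 for replication genes. Fry gave unadjusted p = 0.00596, 0.00834 and 0.0525 and adjusted p = 0.129, 0.129 and 0.405, so none passed. The estimated correlations were 0.522 for mitosis and 0.552 for replication. In the same tumors the adipocyte list mean differed by 1.20 and the keratinocyte list mean by -1.08. The number of mitosis members passing over the list alone was 5 without water replicate 3, 7 without TKI258 replicate 1 or 3, 12 after quantile normalization, 11 with the B cell covariate, and 0 with the variance filter or without both arrays high in B cell markers.

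Lists of matrix protease and myeloid genes had lower means in TKI258 tumors. Of 21 measured protease and inhibitor genes, 17 were lower (mean difference -0.30), and Mmp3 (-1.13 ± 0.12) and the collagenase gene Mmp13 (-1.54 ± 0.35) passed adjusted over the list alone. Mmp9 (-0.68 ± 0.25), Mmp10 (-0.91 ± 0.34) and Plau (-0.42 ± 0.15) did not. The neutrophil list differed by -0.40, with 18 of 23 members lower. Its granule gene Ngp (-1.55 ± 0.25) passed adjusted over the list alone, and Retnlg (-1.33 ± 0.35) and S100a9 (-1.06 ± 0.43) did not. The macrophage list differed by -0.21, with 15 of 17 members lower, led by Gpnmb, Ms4a7, Cx3cr1 and Mertk. The mast cell list differed by -0.45, with 11 of 11 members lower, led by Hdc, Tpsab1, Kit and Ms4a2. Water replicates 2 and 3, which were high in keratinocyte markers (7.29 and 6.98 against 5.39 in water replicate 1), also had the highest protease means (9.08 and 9.13) and neutrophil means (8.23 and 8.19). Water replicate 1, at 8.78 and 7.81, lay below TKI258 replicate 1, at 8.94 and 7.95. Macrophage and mast cell means were highest in water replicate 2 (10.01 and 7.00). Camera gave adjusted p = 4.85e-05, 0.000316, 4.81e-05 and 0.000313 for these lists in that order, and adjusted p = 0.435, 0.435, 0.435 and 0.533 with an estimated correlation. The macrophage and mast cell calls were lost without water replicate 2 (-0.06 and -0.15), where mast cell markers were highest, the mast cell difference was -0.70 without water replicate 1, with 2 members passing over the list alone, and the neutrophil call was lost with the low-signal filter, its difference being -0.24 without TKI258 replicate 3. Protease members passing over the list alone were 5 without TKI258 replicate 1 and 1 without water replicate 2 or 3 or TKI258 replicate 2 or 3, and neutrophil members were 4 without water replicate 1 and 0 without TKI258 replicate 1 or 3.

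Adipocyte genes had a higher list mean in TKI258 tumors. It was 6.76 ± 0.50 in water and 7.96 ± 0.73 in TKI258 tumors (SD, n = 3), with 12 of 13 members higher. The groups overlapped (exact permutation p = 0.2), with water replicate 1 at 7.25 and TKI258 replicate 1 at 7.24. The highest mean of each group was in its tumor with the highest B cell markers, TKI258 replicate 3 (8.71, B cell list 8.75) and water replicate 1 (7.25, B cell list 6.96). The lipid droplet genes Cidec (1.87 ± 0.49) and Plin4 (1.55 ± 0.48), Lep, which encodes leptin (0.76 ± 0.16), Retn (1.56 ± 0.49) and, named after its value was seen, Adipoq (2.12 ± 0.68) passed adjusted over the list alone. Keratinocyte genes were high in 2 of the 3 water tumors (list mean difference -1.08, 15 of 15 members lower), with the smallest p for Dsg3, Lor, Sprr1a and Sprr1b. Their list means were 7.29 and 6.98 in water replicates 2 and 3 but 5.39 in water replicate 1 and 5.28 to 5.57 in TKI258 tumors, and 0 members passed adjusted over the list alone. Camera gave adjusted p = 4.66e-08 for adipocytes and 2.31e-08 for keratinocytes, and adjusted p = 0.435 with an estimated correlation for both. Adipocyte members passing over the list alone were 12 without TKI258 replicate 1, 9 without water replicate 1, 1 without water replicate 3 and 0 without water replicate 2, TKI258 replicate 2 or TKI258 replicate 3. They were 1 after quantile normalization, 0 with array weights, 11 with the variance filter and 12 with the B cell covariate. The keratinocyte difference was -1.67 without water replicate 1, with 13 members passing over the list alone, and -0.71 without water replicate 2.

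**Figure D2:**
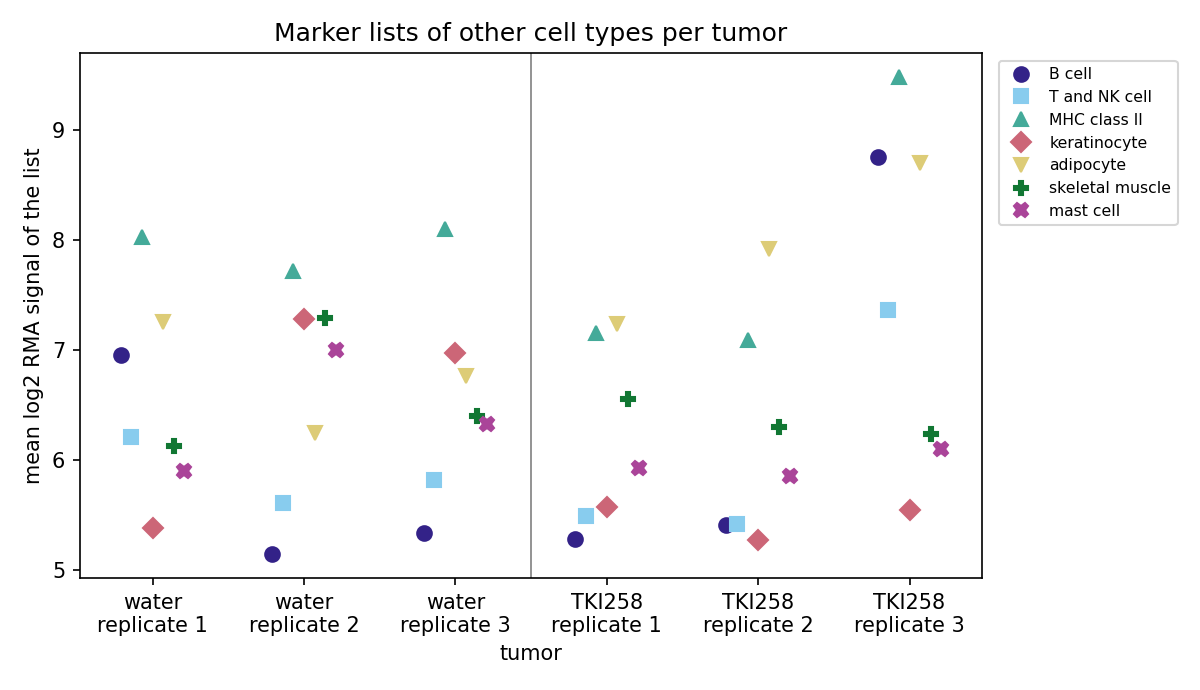
Mean log2 RMA signal (y axis) of 7 marker lists in each of the 6 tumors (x axis), 1 point per list and tumor, with water tumors left of the line and TKI258 tumors right of it. B cell markers stood at 8.75 in TKI258 replicate 3 and 6.96 in water replicate 1 against 5.15 to 5.41 elsewhere, and keratinocyte markers were high in water replicates 2 and 3.

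Lymphoid and interferon lists did not pass, and the difference between groups was below the larger SD within a group for each. The B cell list was 5.81 ± 1.00 in water and 6.48 ± 1.97 in TKI258 tumors (SD, n = 3), the T and NK cell list 5.88 ± 0.30 and 6.09 ± 1.10, the MHC class II list 7.95 ± 0.20 and 7.91 ± 1.36, and the interferon list 7.57 ± 0.25 and 7.43 ± 0.74. Camera adjusted p was 0.157, 0.432, 0.689 and 0.111, and adjusted p = 0.737, 0.892, 0.905 and 0.737 with an estimated correlation. The immunoglobulin genes Ighm and Jchain stood at 9.72 and 9.87 in TKI258 replicate 3, and at 6.84 and 7.42 in water replicate 1. Of the T and NK cell genes Cd5 differed by 0.45 ± 0.45 and Zap70 by 0.33 ± 0.31, of the MHC class II genes H2-Oa by 0.34 ± 0.50 and H2-Ob by 0.41 ± 0.74, and of the interferon genes Oas1a by -0.35 ± 0.18 and Oas2 by -0.37 ± 0.24. Without TKI258 replicate 3 all 4 lists passed lower, with differences of -0.46, -0.42, -0.83 and -0.57 (adjusted p = 0.0158, 2.07e-09, 2.56e-10 and 3.67e-12; ranges over the alternatives 0.00410 to 0.874, 2.07e-09 to 0.789, 2.56e-10 to 1.00 and 2.89e-12 to 0.944), and 8 interferon and 4 MHC class II members then passed adjusted over the list alone. An estimated correlation, which was 0.981, 0.914, 0.924 and 0.810 for these lists with all arrays, was not run without single arrays. Without both TKI258 replicate 3 and water replicate 1, the B cell list did not pass and differed by 0.11 (6 members higher and 6 lower), while the T and NK cell, MHC class II and interferon lists passed lower (-0.26, -0.79 and -0.65), as they did with array weights and with the B cell covariate. The B cell list passed higher without water replicate 1 (1.24), TKI258 replicate 1 (1.27) or TKI258 replicate 2 (1.21), and the T and NK cell list without TKI258 replicate 1 (0.51) or 2 (0.55).

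Lists of stress and metabolism shifted by small amounts. Immediate early genes differed by -0.27, with 12 of 14 members lower and every TKI258 tumor below every water tumor for the list mean. Hspa1a (-0.76 ± 0.21), Dusp1 (-0.67 ± 0.24), Jun (-0.46 ± 0.16) and Fos (-0.45 ± 0.18) led it (camera adjusted p = 0.000138, and adjusted p = 0.435 with an estimated correlation). For this list mean, water replicate 1, at 7.86, lay just above TKI258 replicate 1, at 7.82. Water replicates 2 and 3, the tumors high in keratinocyte markers, stood at 8.04 and 8.13. All 13 measured cholesterol synthesis genes were lower (-0.16), led by Nsdhl, Idi1, Lss and Fdft1 (camera adjusted p = 0.000313, and adjusted p = 0.504 with an estimated correlation). The hypoxia list differed by -0.11, with 16 of 22 members lower, led by Ankrd37, Kdm3a, Adm and Slc2a1 (camera adjusted p = 0.00810, and adjusted p = 0.653 with an estimated correlation). The integrated stress list differed by -0.14, with 11 of 14 lower, led by Ddit3, Dnajb9, Ppp1r15a and Psat1 (camera adjusted p = 0.00996, and adjusted p = 0.617 with an estimated correlation). Oxidative phosphorylation genes differed by -0.06, with 14 of 20 lower, led by Ndufs3, Atp5o, Sdhb and Sdha (camera adjusted p = 0.0220, and adjusted p = 0.625 with an estimated correlation). No member of these 5 lists passed adjusted over the list alone, but 6 immediate early genes did without water replicate 1, 1 without TKI258 replicate 1 or 3, and 1 integrated stress gene without TKI258 replicate 1. The hypoxia and integrated stress calls were lost without water replicate 3 (-0.03 and -0.08) or TKI258 replicate 3 (-0.01 and -0.04), with array weights and with the low-signal filter, hypoxia also with the B cell covariate and integrated stress without both arrays high in B cell markers; the hypoxia difference was -0.19 without water replicate 1 and -0.22 without TKI258 replicate 1, and the integrated stress difference -0.23 without TKI258 replicate 1. The oxidative phosphorylation call was lost without water replicate 2 (-0.03) or TKI258 replicate 3 (-0.03), with the low-signal filter, quantile normalization, array weights and the B cell covariate, its difference was -0.09 without water replicate 1, and the cholesterol difference was -0.09 without water replicate 3 or TKI258 replicate 3.

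The remaining lists did not pass with all arrays. Apoptosis and p53 target genes had a mean difference of 0.07 and a median of -0.01, so the mean and the test (higher) differed in sign from the median. The BH3-only gene Bmf (0.53 ± 0.11) was higher adjusted over the list alone (no member without any 1 array except water replicate 2), and Fas differed by 0.42 ± 0.14. Among FOXO targets (0.13, adjusted p = 0.652), Sesn3 (1.06 ± 0.21) was higher and Ccng2 (-0.43 ± 0.10) lower adjusted over the list alone. No FOXO target passed so without water replicate 3 or any TKI258 replicate, and no lower one without water replicate 2; the list difference was 0.06 without water replicate 3. The fibroblast matrix list differed by 0.17, led by Dcn (0.79 ± 0.23) and Col3a1 (0.51 ± 0.20), with adjusted p = 0.103. It passed higher without water replicate 3 (0.27) or TKI258 replicate 2 (0.23, with 1 member passing over the list alone), with the low-signal filter and after quantile normalization, and differed by 0.09 without water replicate 2. Epithelial genes differed by 0.21 (adjusted p = 0.157), led by the claudin genes Cldn4 (0.91 ± 0.30) and Cldn3 (0.65 ± 0.18), passed higher with the low-signal filter, and had 2 members passing over the list alone without water replicate 1. The epithelial difference was 0.09 without water replicate 2. Mesenchymal regulators differed by -0.09 (adjusted p = 0.0778), with S100a4 and Twist1 at -0.40 ± 0.23 and -0.22 ± 0.14, and passed lower without TKI258 replicate 1 (-0.12) and with the trend and robust prior. Milk genes differed by 0.55 (adjusted p = 0.116), with Csn2 at 4.45 ± 0.15 in water and 5.70 ± 2.03 in TKI258 tumors (SD) and Btn1a1 differing by 0.28 ± 0.19, and passed higher without water replicate 1 (0.85) or TKI258 replicate 1 (0.95), with the variance filter (0.71) and without both arrays high in B cell markers (0.75). The milk gene difference was 0.36 without water replicate 2 and 0.26 without TKI258 replicate 2, with 5 members then higher and 4 lower. Skeletal muscle genes differed by -0.24 (adjusted p = 0.0601), with Mb at 0.30 ± 0.20 and Mylpf at -0.26 ± 0.18. They passed lower without water replicate 1 (-0.48), water replicate 3 (-0.34) or TKI258 replicate 1 (-0.34), with the variance filter (-0.28), after quantile normalization (-0.25) and without both arrays high in B cell markers (-0.42), and differed by 0.10 without water replicate 2, where their mean was 7.29 against 6.13 to 6.56 elsewhere. Erythroid genes, with Epb42 at 0.18 ± 0.12 and Alas2 at -0.63 ± 0.29, had a mean difference of -0.04, against a median and a test that were higher (adjusted p = 0.838).

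**Figure D3:**
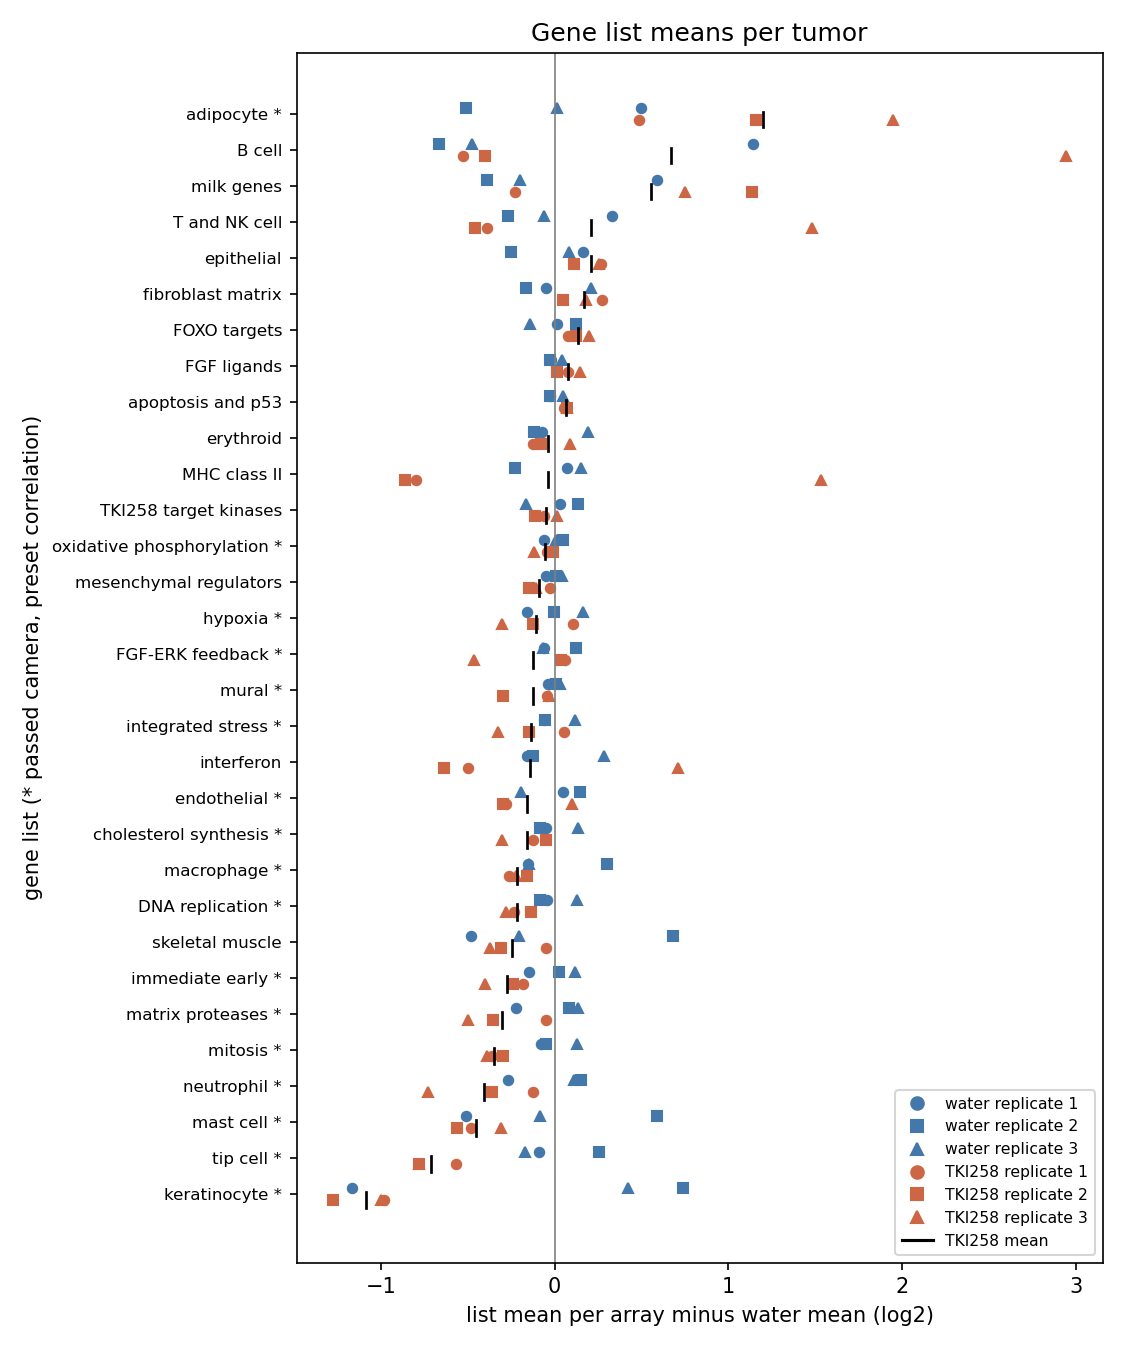
Mean log2 signal of each of the 31 gene lists (y axis) in each tumor minus the mean of the water tumors (x axis, log2), with water tumors in blue, TKI258 tumors in orange and their mean as a black line; a star marks the 17 lists that passed camera with the preset correlation, none of which passed with an estimated one. The tip cell, mitosis, DNA replication, macrophage and immediate early lists had every TKI258 tumor below every water tumor. For macrophages this was narrow, with list means of 9.5481 in water replicate 1 and 9.5418 in TKI258 replicate 2. The apoptosis and p53 list narrowly had every TKI258 tumor above every water tumor (7.8094 in TKI258 replicate 1, 7.8045 in water replicate 3).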

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

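The restriction to probe sets with 1 gene, the removal of both arrays with high B cell markers and the B cell covariate were chosen only after the data were seen. The cause of the changes listed here was not tested, except that filters and left-out arrays leave fewer probe sets or tumors to test. Of 17 list calls, those of mitosis, DNA replication, tip cell, adipocyte, keratinocyte, matrix protease, immediate early and cholesterol synthesis genes kept direction and threshold under each processing alternative that gave a value. The others were lost or turned under at least 1, and none held with an estimated correlation or fry. Named genes gave 1930 results on the same side as with all arrays, 2 newly past the threshold and 38 with another sign. As no named gene passed with all arrays, the same side here means the same sign and again not past the threshold. Lists gave 463 on the same side, 36 newly past it, 63 no longer past it and 20 with another sign. List results with an estimated correlation or fry used the all-array difference, so their sign could not change.

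Probe sets that passed numbered 0 with limma (2803 at unadjusted p under 0.05), 2 with the variance filter (both lower), 1 without both arrays with high B cell markers (lower), and 0 to 3 when 1 array was left out (lower ones also 0 to 3). Lists that passed numbered 11 with the low-signal filter, 0 with an estimated correlation, 0 with fry, and 11 to 21 when 1 array was left out. Neither scaling alternative moved the median of all probe sets by over 0.1. That median cannot show a shift that depends on signal. Among the brighter probe sets kept by the low-signal filter, 532 were higher and 956 lower at unadjusted limma p under 0.05 (median difference -0.0267). Over all probe sets these counts were 1344 and 1459 (median 0.0158). How far small negative list differences follow signal level was not tested apart from that filter. The B cell list has no value with its own mean as covariate, which fixes it at 0, and lists with fewer than 5 members after a filter were not tested.

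These log2 differences changed sign. With the low-signal filter, skeletal_muscle was 0.00927. With quantile normalization Flt4 was -0.0199, and with median centring Fgfr1 was -0.0169. With array weights the lists fgf_erk_feedback, t_nk_cell and b_cell were 0.0127, -0.230 and -0.188, and Dusp6, Etv5, Flt4, H2-Oa, H2-Ob and Pdgfrb were 0.0157, 0.000619, -0.0622, -0.114, -0.186 and 0.0849. Without both arrays with high B cell markers, fgf_erk_feedback, t_nk_cell, Etv5 and H2-Ob were 0.0195, -0.258, 0.0681 and -0.0805. With the B cell covariate, t_nk_cell, Fgfr1, Flt4 and H2-Ob were -0.127, -0.000818, -0.0696 and -0.0923.

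When 1 array was left out, lists that changed sign ranged as follows: tki258_target_kinases -0.133 to 0.0151, fgf_erk_feedback -0.214 to 0.0485, interferon -0.567 to 0.106, mhc_class_ii -0.827 to 0.369, t_nk_cell -0.423 to 0.548, b_cell -0.463 to 1.27, skeletal_muscle -0.482 to 0.0983 and erythroid_blood -0.0995 to 0.0586. Genes ranged as follows: Acta2 -0.374 to 0.00767, Cd5 -0.0667 to 0.745, Dusp6 -0.153 to 0.0233, Etv5 -0.223 to 0.0769, Fgfr1 -0.0766 to 0.0819, Fgfr3 -0.0773 to 0.00143, Flt4 -0.111 to 0.139, H2-Oa -0.237 to 0.671, H2-Ob -0.463 to 0.909, Kdr -0.250 to 0.0385, Pdgfra -0.318 to 0.553, Pdgfrb -0.458 to 0.0441, Pecam1 -0.535 to 0.0767, Vegfa -0.161 to 0.184 and Zap70 -0.0367 to 0.532.

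With the replicate number as a block 0 probe sets passed (limma, 2712 at unadjusted p under 0.05) and 22 lists, but the numbers do not pair the tumors: correlations of deviations between like-numbered tumors were -0.232, 0.186 and 0.00897. Signal over background could not be tested, since detection calls were not used here.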

Other observations

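The tests of dilution by other tissue, of lymphoid tissue as a source of the mitosis difference and of endothelial cell number, and the genes of the next paragraph, were chosen only after the results were seen. The counts of the real split were known before the splits were tested.

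Genes outside the rule were looked for among those with a mean signal above 7, an unadjusted limma p under 0.01 and no overlap between tumors of the groups. There were 176 such genes, 47 higher and 129 lower, and those named here were picked from them by their known roles after their values were seen. None passed over all probe sets. The growth factor genes Pdgfc (1.45 ± 0.29, log2 difference ± SE, adjusted p = 0.484) and Vegfc (1.14 ± 0.30, adjusted p = 0.567) were higher in each TKI258 tumor than in any water tumor. Others that were higher were Hp (1.75 ± 0.45), Serpina3n (1.70 ± 0.41), Lrg1 (1.25 ± 0.23), Steap4 (1.10 ± 0.25), C4b (0.95 ± 0.26), Irs1 (0.87 ± 0.19), Ghr (0.59 ± 0.15), Egfr (0.66 ± 0.14) and Esr1 (0.47 ± 0.09). The imprinted gene Mest (-1.55 ± 0.25), the bone sialoprotein gene Ibsp (-1.83 ± 0.36) and Sema3e (-0.80 ± 0.19) were lower in each. The screen itself fixed that these genes do not overlap, and no group of them was tested.

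With 3 tumors against 3 there are 10 splits of the arrays, too few for a share under 0.05. The real split gave 0 probe sets with limma (2803 at unadjusted p under 0.05) and the highest other 0; with a real count of 0, all 10 must give as many, so this comparison says nothing. The real split gave 2803 probe sets with unadjusted p under 0.05 and the highest other 2275, so 1 of the 10 gave as many, the real split itself. It gave 17 gene lists and the highest other 21, so 3 of the 10 gave as many, the real split included. Every other split also gave at least 8 with the preset correlation.

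Lymphoid markers were high in TKI258 replicate 3 and keratinocyte markers in water replicates 2 and 3. A list of lymph node stroma and vessel genes, 9 of 12 measured, was 1.39 log2 higher in TKI258 replicate 3 than in the next TKI258 tumor, which is consistent with lymph node tissue in that sample; Glycam1, also on the milk gene list, was 12.1 there, 10.3 in water replicate 1 and 4.78 to 6.12 elsewhere, and Cxcl13 was 10.8 and 9.04 in these tumors. Immune aggregates within the tumor stay open. For skin, the hair, cornified layer and pigment list was 0.341 higher in the lower of water replicates 2 and 3 than in water replicate 1, between the bounds set for and against, so skin and keratinocyte-like tumor cells cannot be told apart; Hrnr and Krt77 (7.68 and 7.29 in water replicate 2, 5.58 and 5.50 in water replicate 1) were high there, and hair keratins were not. No biological explanation was tested for either.

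The mitosis list was lower under TKI258. Lymphoid tissue in 1 array of each group is argued against, since 105% of the difference was kept without both arrays, although with 2 tumors against 2 no member then passed over the list alone. Fewer tumor cells could lower the list: 5 luminal keratin and adhesion genes differed by 0.116 (exact permutation p = 0.6), and their mean minus the mitosis mean differed by 0.463 (exact permutation p = 0.2), with the lowest TKI258 value below the highest water value (-0.192). By overlap alone, the first reading, this test counted for dilution, and it was changed to undecided after its value was seen. The 5 genes went both ways (Krt18 -0.32 and below water in each TKI258 tumor, Krt8 -0.13, Krt19 0.19, Cdh1 0.27, Epcam 0.57), so dilution and lower expression of the list cannot be told apart. Krt19 was highest in the tumors high in B cell markers, water replicate 1 (8.64) and TKI258 replicate 3 (9.07), against 6.85 to 7.43 elsewhere. The 5 genes may therefore not follow tumor cells alone. An effect of TKI258 on cell division stays open, untested.

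The tip cell list was lower under TKI258, with a member median of -0.55 against -0.15 for the endothelial list. Fewer endothelial cells as the whole cause would need endothelial genes to be lower by about as much. With all arrays the gap between these medians, 0.405, exceeded the SD of the endothelial members, 0.299, the bound set against this cause. That SD is a spread between genes, not between tumors, so it gives no error for the gap. Without TKI258 replicate 3, the tumor high in lymphoid markers, the gap was 0.243 and the SD 0.282, a margin of -0.0386, so the explanation cannot be told apart from lower expression per cell. Whole tumors were profiled, and a change of these genes in cells other than endothelium was not tested. An earlier test on the same question was undecided too: tip cell minus endothelial means were 0.677 ± 0.125 in water and 0.126 ± 0.303 in TKI258 tumors (SD, n = 3, exact permutation p = 0.1, the smallest possible), with a gap of 0.155 between the closest tumors. An effect of TKI258 on sprouting vessels stays open, untested.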
